A study of Mus musculus with 8 samples.

How the data were processed

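RNA from 8 cultures of the mouse pre-B cell line wk3 was hybridised by the authors to one-colour Cy3 Agilent gene expression arrays, 1 array per culture without pooling. The groups were scrambled sponge with IL-7, miR-15 sponge with IL-7, and each of these 36 h after IL-7 withdrawal, with 2 replicates per group. According to the study's description, the replicates came from separate experiments with independently generated clones, which implies that replicate number pairs the groups. The correlations of the replicates' deviations between groups were low (0.0178 to 0.131), so the pairing, and with it the replicate block, rests on that description alone. All 8 arrays lay on 1 slide and were read in 1 scan. The arrays with IL-7 were in slide column 1 and those without in column 2, and the 4 slide rows held scrambled replicates 1 and 2 and then sponge replicates 1 and 2. Slide position could therefore not be separated from IL-7 or from the construct.

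The deposited scanner tables give a processed signal in intensity units on a linear scale, with flags per spot, which per the file headers is background subtracted with spatial and multiplicative detrending within the array and not normalized between arrays. Extraction used Agilent Feature Extraction, version 10.7.1.1 in the submitters' processing notes and 10.7.3.1 in the file headers. The deposited value table of the series also holds intensity on a linear scale and has the same distribution in every array, which is the property of quantile normalization. The software behind it is not stated. Per array, 50.6%, 53.0%, 54.0%, 53.3%, 55.3%, 55.7%, 54.7% and 56.6% of the 59305 non-control spots were well above background by the deposited flags (scrambled with IL-7 replicates 1 and 2, sponge with IL-7 replicates 1 and 2, then the same without IL-7). The 75th percentile of the signal was 297 to 410, the median local background 17 to 20, and 0 spots were saturated.

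For the values in the report, spots flagged as non-uniform or as population outliers (128 to 277 per array) and control spots were removed, and the log2 processed signal minus the array's 75th percentile was averaged over the spots of a probe. A probe was kept if it was well above background on both arrays of at least 1 group, which kept 30963 of 55681 probes. Probes were named from the deposited annotation with a table of mouse gene symbols, 27235 by accession, 3581 by symbol and 565 by synonym. Of the 24300 unmatched probes, 16251 belong to regions of long intergenic RNAs. The kept probe with the highest mean over the 8 arrays represented each gene, which gave 21320 genes or features. Probe positions are on mm9 as deposited, and no genome sequence or transcript annotation was at hand, so no exon or untranslated region was assigned.

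A linear model of the 4 group means was fitted with limma 3.58.1 in R 4.3.3, with moderated statistics (residual degrees of freedom 4, prior 1.812), two-sided tests and Benjamini-Hochberg adjustment over all genes of a contrast. A gene was called at an adjusted p under 0.05. The 6 contrasts were withdrawal in scrambled cells, withdrawal in sponge cells, sponge minus scrambled with IL-7, without IL-7 and averaged over both, and the difference between the withdrawal effects. Of 25 gene lists fixed from general knowledge, the 24 with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the 24 lists within a contrast. The lists were also tested with camera at an estimated correlation, under which 0 lists passed in any contrast, and with fry. At the preset correlation, 12 lists passed for withdrawal in scrambled cells, 14 in sponge cells, 11 for the sponge with IL-7, 11 without, 12 averaged and 8 for the difference. The list of published miR-15 family targets was drawn from the literature by memory and shares members with the cell cycle lists. Correlations over genes and the overlap of called genes describe similarity only.

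Named genes followed a fixed rule, and not all genes it took are reported here. For each withdrawal contrast it took the 8 largest rises and 8 largest falls among called genes with a symbol and with non-overlapping arrays, and for the other contrasts the 6 largest in each direction. It added up to 4 called members of each list that passed, up to 2 members of smallest p of each other list, and 16 genes fixed for every comparison. Where a gene was well above background on 0 arrays of a group, that group was set to its arrays' floor, the lowest normalized signal among probes well above background on the array (-5.60 to -5.06), and the fold is given as at least that value. The groups, contrasts, lists, rule and most alternatives were fixed before the data were examined.

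On simulated data with the spread of these arrays and 200 genes changed at each size, the procedure was tested at log2 changes of 0.5, 1 and 2. It recovered 32.0% to 37.0%, 65.0% to 70.0% and 85.0% to 87.0% in the withdrawal contrasts and the contrasts of the sponge in 1 condition, 53.0%, 83.0% and 91.5% in the averaged contrast, and 10.0%, 44.5% and 75.5% for the difference between withdrawal effects. False calls were 3.62% to 8.27% of the calls. In the simulation each gene had the same spread in all groups, and genes varied independently without clone effects. Fewer genes changed than were called in most contrasts of the data. The percentages therefore describe the simulation and may differ from those of the real contrasts.

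The alternatives changed the background and scaling (normexp with an offset of 50, quantile normalization, the median of probes well above background on all arrays, the deposited value table), the filter, the probe summary, the replicate block, the moderation, the threshold, the arrays used and the list test, and left out each array in turn. With an array left out, 1 group holds a single array, which is assumed to vary like the other groups. One further setting, chosen after seeing the data, left out probes that hold an 8-base word shared among the construct-specific features or the 7-base miR-15 seed match. Tables were handled with the package data.table (version 1.17.8) and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. Tests of seed matches in 3′ untranslated regions were left out because no sequence for them was at hand.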

Results

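Gene expression was measured in wk3 cells, a mouse pre-B cell line that lacks the adaptor protein SLP-65 and grows in interleukin 7 (IL-7), the cytokine that sustains early B cell precursors. A microRNA sponge is a transcript with many binding sites for a microRNA family, which it keeps away from the family's other targets. The cells carried a sponge for the miR-15 family or a scrambled sponge as the control, and RNA was taken with IL-7 present or 36 h after its withdrawal, the step that starts pre-B cell differentiation in this line. Each of the 4 groups held 2 arrays from independently generated clones, so the number of arrays limits the precision of every value. On the 8 arrays, 50.6% to 56.6% of the 59305 non-control spots lay well above background, and 21320 genes or annotated features were tested. Pearson's r between the 2 replicates, across genes, which are not independent of one another, was 0.990 for scrambled cells with IL-7, 0.995 for sponge cells with IL-7, 0.997 for scrambled cells without IL-7 and 0.996 for sponge cells without IL-7. The scrambled cells with IL-7 were the most variable group, with 1168 genes more than 1 log2 unit apart between replicates, against 193 to 519 in the other groups. Of the variance across arrays, the first principal component held 59.65% and the second 18.13%. Changes are log2 differences ± SE with n = 2 arrays per group, and adjusted p values come from limma. The SE of a gene rests on its spread over all 4 groups together, which the fit takes as equal between groups. It may be too small where the most variable group is compared and too large elsewhere.

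The first comparison asked which genes change in control cells when IL-7 is withdrawn. Genes of immunoglobulin recombination and B cell maturation rose, and genes of DNA replication, mitosis, ribosome biogenesis and cholesterol synthesis fell. Rag1, a subunit of the recombinase that joins antigen receptor gene segments, rose by 3.59 ± 0.27 (adjusted p = 0.00037), and its partner Rag2 rose by 2.21 ± 0.18. Igkc, the constant region of the kappa light chain, rose by 2.77 ± 0.17 (adjusted p = 0.00027). Ccne1, which encodes cyclin E1 and is a published miR-15 family target, fell by 3.37 ± 0.30 (adjusted p = 0.000574), and the growth regulator Myc fell by 2.67 ± 0.09 (adjusted p = 0.000234). In all, 10251 of the 21320 genes passed, 4414 higher and 5837 lower, of which 1223 and 1558 changed by 2-fold or more. The larger direction depended on the scaling between arrays, with 5271 higher and 4971 lower after quantile normalization and 5253 and 4960 in the deposited value table.

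Among genes that fell in control cells, all 28 measured DNA replication genes were lower, 28 also when adjusted over the list alone (mean -2.20, camera adjusted p = 5.72e-13). They included the helicase subunit Mcm6 (-2.87), the licensing factor Cdc6 (-3.05) and Gins2 (-3.05). All 29 mitosis genes were lower, 29 when adjusted over the list alone (mean -1.43, adjusted p = 6.11e-12). Top2a stood at -1.72 and the transcription factor Foxm1 at -1.72, and the kinase Aurkb was at least 3.66-fold lower. Of 16 G1/S cyclins, kinases and E2F factors, 15 fell and 0 rose, 15 and 0 when adjusted over the list alone (mean -1.47, adjusted p = 4.2e-07). E2f1 fell by 2.15 and E2f7 by 2.27 (its 2 kept probes between -2.27 and -1.05). Of 27 published miR-15 family targets, 17 fell and 2 rose, 17 and 3 when adjusted over the list alone (mean -0.82, adjusted p = 5.83e-04). The kinase Wee1 fell by 1.57 and the spindle protein Nusap1 fell by 1.59. All 4 of these lists lost their call with an estimated correlation (adjusted p = 0.323 with an estimated correlation, for each). Of 22 MYC-responsive and ribosome biogenesis genes, 13 fell and 1 rose, 14 and 1 when adjusted over the list alone (mean -0.49, adjusted p = 0.00153, and adjusted p = 0.323 with an estimated correlation). The nucleotide kinase Nme1 fell by 1.34, its 3 kept probes lying between -1.34 and -0.34. Of 19 cholesterol synthesis enzymes, 18 fell and 0 rose, 19 and 0 when adjusted over the list alone (mean -1.02, adjusted p = 2.9e-08, and adjusted p = 0.137 with an estimated correlation), and Fdps fell the most (-1.84). Of 17 glycolysis genes, 9 fell and 2 rose, 10 and 2 when adjusted over the list alone (mean -0.39, adjusted p = 0.0313, and adjusted p = 0.426 with an estimated correlation), with Gapdh at -1.22. Glycolysis lost its call after quantile normalization and in the deposited value table.

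Among genes that rose in control cells, 15 of 18 immature and mature B cell markers were higher and 0 lower, 15 and 0 when adjusted over the list alone (mean 1.71, adjusted p = 8.16e-08). They included the co-stimulatory receptor Cd40 (4.31 ± 0.22) and Cd74, the invariant chain of MHC class II (3.86 ± 0.18). Ms4a1, which encodes CD20, rose by 3.15 ± 0.76 from a level measured well above background on 1 of 2 arrays with IL-7. Of 18 pre-B differentiation factors, 13 rose and 1 fell, 13 and 1 when adjusted over the list alone (mean 0.68, adjusted p = 1.33e-04). The transcription factors Irf4 and Foxo1 rose by 1.2 and 0.81. Of 21 lysosome and autophagy genes, 11 rose and 0 fell, 12 and 0 when adjusted over the list alone (mean 0.58, adjusted p = 8.36e-05). The protease Ctss rose by 1.51. Of 7 plasma cell markers, 5 rose and 1 fell, 6 and 1 when adjusted over the list alone (mean 0.54, adjusted p = 0.0313). Prdm1, a regulator of plasma cell fate, rose by 1.36. Of 18 interferon response genes, 7 rose and 1 fell, 7 and 1 when adjusted over the list alone (mean 0.38, adjusted p = 0.0464, and adjusted p = 0.0634 with replicate as a block). Among them Mx2 rose by 1.26. The interferon list lost its call after quantile normalization and in the deposited value table. None of these 5 lists passed with an estimated correlation (adjusted p = 0.323 with an estimated correlation, for each).

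Of the other genes fixed for every comparison, Bcl2, the survival factor, fell by 1.84 ± 0.09 in control cells. The cyclin gene Ccnd2 fell by 1.05 ± 0.13, Cdk6 fell by 0.85 ± 0.16 and Ccnd3 fell by 0.68 ± 0.10. Smc4, a host gene of miR-15b and miR-16, fell by 1.13 ± 0.12, and Dleu2, the host gene of miR-15a and miR-16, gave 0.43 (adjusted p = 0.123). Cish, a feedback inhibitor of cytokine signalling, rose by 1.35 ± 0.10, and its relative Socs2 rose by 0.24 (adjusted p = 0.0491, and adjusted p = 0.0676 with replicate as a block). The 4 kept probes of Socs2 lay between -0.02 and 0.78. Blnk, the gene deleted in this line, rose by 0.73, where the position of its probe relative to the deletion is unknown. Its signal was high in all 4 groups, with group means of 7.16 to 8.22 above the array's 75th percentile. Igll1, a surrogate light chain gene, fell by 0.39, a change whose sign turned under quantile normalization (0.02), and Il7r gave 0.06 (adjusted p = 0.593). Other called genes that fell included Tbxas1, at least 45.8-fold, Strip2, at least 21.6-fold, and Scarf1, at least 16.2-fold. Those that rose included Lrrc15, at least 15.5-fold, Bcl3 (4.58 ± 0.23, well above background on 1 of 2 arrays with IL-7), Agbl1, at least 11-fold, and Prm1 (4.51 ± 0.21). In sponge cells Tbxas1, Strip2 and Scarf1 gave -1.72, -0.18 and -1.40 on withdrawal. With IL-7 present, sponge minus scrambled cells gave -5.78, -3.91 and -4.60 for them. Their signal was thus highest in scrambled cells with IL-7, the most variable group.

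The remaining lists did not pass in control cells. Of 16 CDK inhibitors and quiescence genes, 7 were higher and 5 lower, 7 and 5 when adjusted over the list alone (adjusted p = 0.743). Their mean was -0.02, their median 0.14 and the test pointed upward, with the quiescence factor Klf2 at 2.62 and the inhibitor Cdkn1a at -1.83 (its 3 kept probes between -1.83 and -0.26). The IL-7 receptor and STAT5 pathway (19 genes) had 9 higher and 4 lower (10 and 4 when adjusted over the list alone, adjusted p = 0.0903), with Il2ra at 2.37. The pre-BCR and B lineage signalling list (17 genes) had 7 higher and 3 lower (adjusted p = 0.198). The p53 targets (16) had 9 and 3 (adjusted p = 0.0866). Apoptosis regulators (16) had 6 and 6 (adjusted p = 0.914) and the unfolded protein response (17) had 2 and 8 (adjusted p = 0.121). Heat shock and immediate early genes (12) had 5 higher and 5 lower, with a mean of 0.43, a median of -0.13 and adjusted p = 0.821. MicroRNA processing genes (13) had 7 and 4 (adjusted p = 0.445), with the microprocessor subunits Dgcr8 at -0.95 and Drosha at -0.66. T cell markers (6 measured) had 2 higher and 2 lower (adjusted p = 0.819), and myeloid markers (9) had 2 and 1 (adjusted p = 0.651). NK cell markers (5) were at 2 and 1 (adjusted p = 0.826) and erythroid markers (7) at 1 and 1 (adjusted p = 0.862). Of the fibroblast markers, 3 were measured and 0 called, with a mean of 0.10, too few for camera. When adjusted over the list alone, the counts were 6 and 7 for apoptosis regulators, 2 and 9 for the unfolded protein response, 8 and 4 for microRNA processing, 1 and 0 for myeloid and 2 and 2 for NK markers, and the same as above for the others. Mean, median and test did not share a sign for the T cell, NK and erythroid lists either. The count of called genes moved by more than 1.5 times without scrambled cells without IL-7 replicate 2, to 6770.

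**Figure D1:**
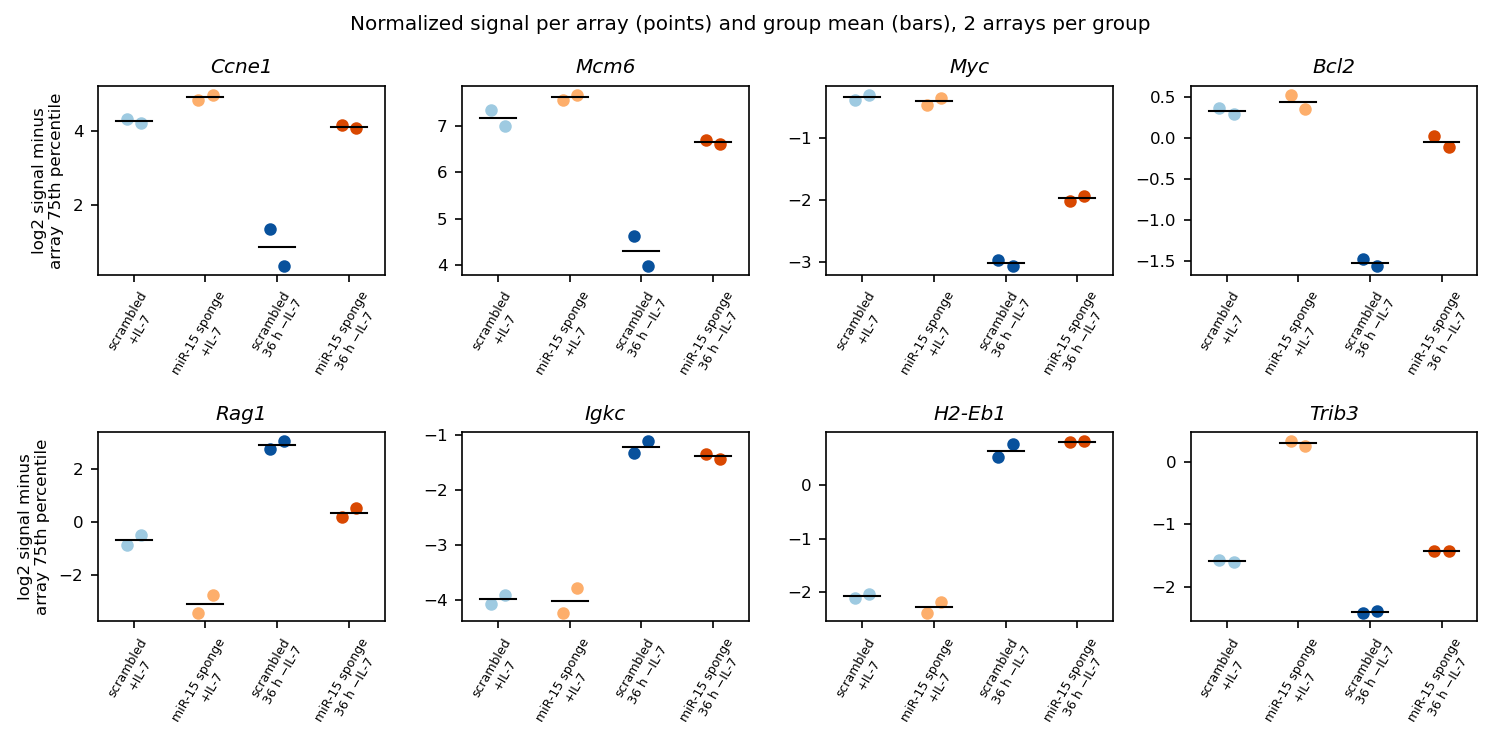
Signal of 8 genes on each of the 8 arrays (y axis, log2 signal minus the array's 75th percentile) in the 4 groups (x axis), with points for single arrays and bars for group means. Ccne1 fell by 3.37 on withdrawal in scrambled cells and differed by -0.79 in sponge cells, while Rag1 rose by 3.59 and 3.43.

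The second comparison asked the same of cells with the miR-15 sponge. Recombination and maturation genes rose in these cells too, and DNA replication, cholesterol synthesis and ribosome biogenesis genes fell. Rag1 rose by 3.43 ± 0.27 (adjusted p = 0.00225), Igkc by 2.63 ± 0.17 (adjusted p = 0.00163) and the MHC class II gene H2-Eb1 by 3.1 ± 0.11 (adjusted p = 0.00159). Myc fell by 1.57 ± 0.09 (adjusted p = 0.00159), while Ccne1 gave -0.79 ± 0.30 and did not pass (adjusted p = 0.121). The Ccne1 values of sponge cells did not overlap, at 4.82 and 4.96 with IL-7 and 4.15 and 4.06 without. Its SE also takes in the scrambled arrays without IL-7, which lay at 1.38 and 0.38. In all, 4939 genes passed, 1689 higher and 3250 lower, of which 370 and 229 changed by 2-fold or more. The share of called genes that were higher, 34.2%, depended on the scaling between arrays, being 51.2% after quantile normalization and 51.5% in the deposited value table.

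Of the lists that fell in sponge cells, DNA replication had 18 of 28 genes lower and 0 higher, 28 and 0 when adjusted over the list alone (mean -0.77, adjusted p = 1.37e-08, and adjusted p = 0.416 with an estimated correlation). Gins2 fell by 1.26 and the licensing factor Cdt1 fell by 1.03. Of 16 G1/S genes, 8 fell and 0 rose, 10 and 0 when adjusted over the list alone (mean -0.56, adjusted p = 8.64e-05, and adjusted p = 0.378 with an estimated correlation). Mitosis genes passed as a list (mean -0.32, adjusted p = 6.58e-04) with 3 of 29 lower, 0 when adjusted over the list alone. The adjusted p = 0.607 with an estimated correlation, and after quantile normalization mitosis genes did not pass (-0.09, adjusted p = 0.494). Published miR-15 family targets had 7 of 27 lower and 0 higher, 7 and 0 when adjusted over the list alone (mean -0.32, adjusted p = 0.0051, adjusted p = 0.416 with an estimated correlation, and 0.0682 after quantile normalization). The G protein Arl2 fell by 0.64 and the growth factor Vegfa fell by 0.61. MYC-responsive genes had 12 of 22 lower and 0 higher, 16 and 0 when adjusted over the list alone (mean -0.41, adjusted p = 3.55e-05), with the nucleolar protein Npm1 at -0.92. Cholesterol synthesis had 16 of 19 lower and 0 higher, 16 and 0 when adjusted over the list alone (mean -0.61, adjusted p = 1.94e-08, and adjusted p = 0.131 with an estimated correlation), with Fdps at -1.0. Glycolysis had 6 of 17 lower and 0 higher, 7 and 0 when adjusted over the list alone (mean -0.30, adjusted p = 0.00294), but did not pass after quantile normalization (-0.13, adjusted p = 0.055). For the MYC-responsive and glycolysis lists, adjusted p = 0.378 with an estimated correlation.

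Of the lists that rose in sponge cells, immature and mature B cell markers had 14 of 18 higher and 0 lower, 15 and 1 when adjusted over the list alone (mean 1.32, adjusted p = 4.37e-10, and adjusted p = 0.212 with an estimated correlation). Cd40 rose by 3.53 and Cd74 by 3.29. Pre-B differentiation factors had 8 of 18 higher and 1 lower, 8 and 1 when adjusted over the list alone (mean 0.52, adjusted p = 7.19e-05), with Irf4 at 0.94. CDK inhibitors and quiescence genes had 6 of 16 higher and 1 lower, 6 and 1 when adjusted over the list alone (mean 0.34, adjusted p = 0.00946). The antiproliferative gene Btg2 rose by 2.03 and Klf2 by 1.78. Lysosome and autophagy genes had 6 of 21 higher and 0 lower, 6 and 0 when adjusted over the list alone (mean 0.26, adjusted p = 2.76e-04, and adjusted p = 0.388 with an estimated correlation). The sialidase Neu1 rose by 1.09. Interferon response genes had 6 of 18 higher and 1 lower, 6 and 1 when adjusted over the list alone (mean 0.31, adjusted p = 0.0113). The p53 targets had 2 of 16 higher and 0 lower, 2 and 0 when adjusted over the list alone (mean 0.24, adjusted p = 0.0231), with Plk2 at 1.95. Plasma cell markers had 2 of 7 higher and 1 lower, 4 and 1 when adjusted over the list alone (mean 0.33, adjusted p = 0.0302). For the pre-B, CDK inhibitor, interferon, p53 and plasma cell lists, adjusted p = 0.378 with an estimated correlation.

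Among the genes fixed for every comparison, Bcl2 fell by 0.49 in sponge cells, Ccnd2 fell by 1.29 and Cdk6 fell by 0.67. Ccnd3 gave -0.23 (adjusted p = 0.138) and Smc4 -0.32 (adjusted p = 0.119). Rag2 rose by 2.06, Cish by 1.06 and Blnk by 0.51. Il7r (0.04), Socs2 (-0.02, its probes between -0.09 and 0.29), Igll1 (-0.33) and Dleu2 (0.21) did not pass. Other called genes that rose included Prm1 (3.38), Agbl1, at least 2.36-fold, Fcmr, the Fc receptor for IgM, at least 2.96-fold, and Scimp, at least 5.19-fold. Those that fell included Cst7, which encodes cystatin F, at least 7.26-fold, Tac4 (-2.38), Plb1, at least 1.75-fold, and Myl10 (-2.21). The lists that did not pass were the IL-7 receptor and STAT5 pathway (4 higher and 3 lower, adjusted p = 0.176), pre-BCR signalling (5 and 2, adjusted p = 0.246) and apoptosis regulators (2 and 4, adjusted p = 0.911). Nor did the unfolded protein response (0 and 5, adjusted p = 0.26), heat shock genes (3 and 1, adjusted p = 0.496) or microRNA processing genes (0 and 3, adjusted p = 0.496) pass. The same held for T cell (0 and 1, adjusted p = 0.426), myeloid (1 and 1, adjusted p = 0.911), NK (1 and 1, adjusted p = 0.971) and erythroid markers (0 and 1, adjusted p = 0.483). Of the 3 fibroblast markers, 0 were called (mean -0.26). When adjusted over the list alone, the counts were 5 and 4 for the IL-7 receptor and STAT5 pathway, 6 and 3 for pre-BCR signalling, 4 and 5 for apoptosis regulators, 1 and 5 for the unfolded protein response and 3 and 3 for heat shock genes, and the same as above for the others. Mean, median and test did not share a sign for the apoptosis, heat shock, T cell, myeloid and NK lists. The count of called genes fell to 2982 and 1856 without sponge cells with IL-7 replicates 1 and 2, and to 2399 and 1738 without sponge cells without IL-7 replicates 1 and 2.

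Across genes, the withdrawal changes of the 2 constructs had a Pearson correlation of 0.728 and a Spearman correlation of 0.737, where genes are not independent replicates. Of the 4478 genes called in both, 4464 had the same sign and 14 the opposite. Among the 801 genes whose mean fall over both constructs was at least 1, 91.4% fell less in sponge cells, with a median ratio of sponge to scrambled change of 0.441. Among the 739 genes with a mean rise of at least 1, 89.2% rose less, with a median ratio of 0.646. By list, the ratio of mean changes was 0.228 ± 0.086 for mitosis, 0.350 ± 0.083 for DNA replication, 0.600 ± 0.028 for cholesterol synthesis and 0.773 ± 0.076 for immature and mature B cell markers.

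**Figure D2:**
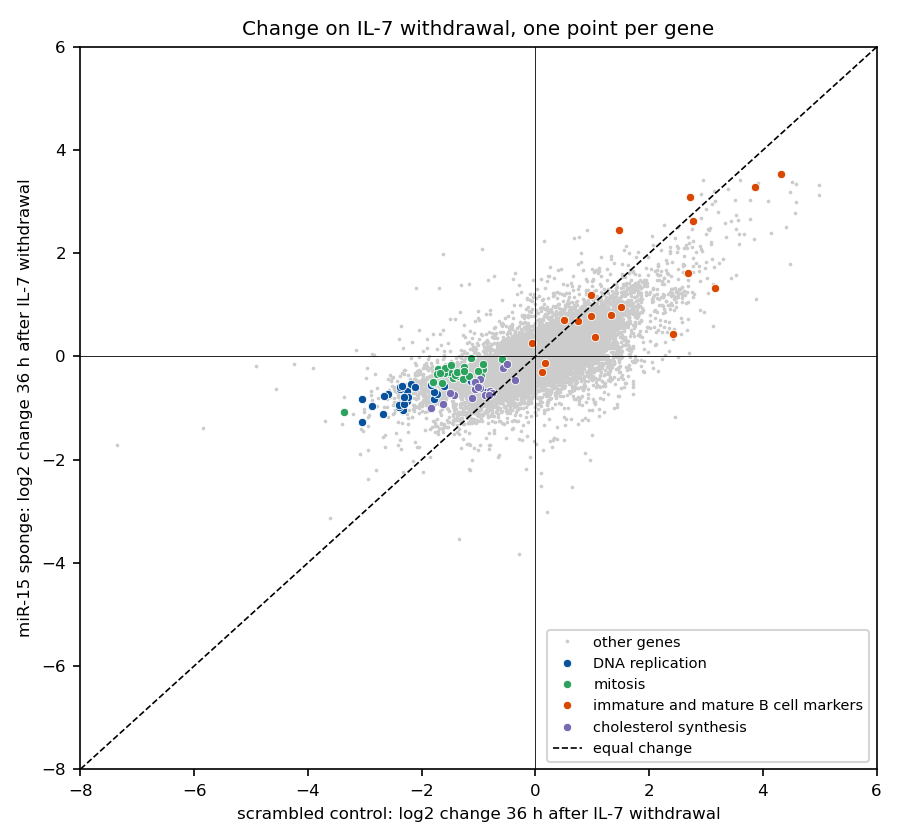
Withdrawal change in scrambled cells (x axis, log2) against that in sponge cells (y axis, log2), 1 point per gene, with 4 gene lists coloured and a dashed line of equal change. Across the 21320 genes the Pearson correlation was 0.728, and DNA replication genes averaged -2.20 on the x axis and -0.77 on the y axis.

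The third comparison set the miR-15 sponge against the scrambled sponge with IL-7 present. Few single genes passed, and those that did included lower recombination genes and higher unfolded protein response genes. Rag1 was lower by 2.39 ± 0.27 on the log2 scale (-2.39, adjusted p = 0.0253) and Rag2 by 1.56 ± 0.18 (-1.56, adjusted p = 0.0287) with the sponge. Trib3 (1.88 ± 0.07, adjusted p = 0.00045), Chac1 (2.03 ± 0.14, adjusted p = 0.00567) and Asns, which encodes asparagine synthetase (1.63 ± 0.11, adjusted p = 0.00575), were higher. Cish was lower (-1.04 ± 0.10, adjusted p = 0.0155), and Ccne1 gave 0.64 ± 0.30 (adjusted p = 0.307). The Ccne1 values did not overlap here either, at 4.30 and 4.20 in scrambled and 4.82 and 4.96 in sponge cells. Its SE again takes in the scrambled arrays without IL-7. In all, 241 genes passed, 67 higher and 174 lower, of which 33 and 79 changed by 2-fold or more, and 151 passed (36 higher and 115 lower) with replicate as a block. With only the arrays compared, 32 of the 34 named called genes lost their call.

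Several lists shifted together with IL-7 although few of their members passed alone. Of the 11 lists called in this comparison, 3 lost their call with no filter on dim probes. Some also lost it when single arrays were left out. With fry, which tests a list by itself, the target, G1/S, DNA replication, CDK inhibitor, pre-B, pre-BCR, mature B cell and lysosome lists did not pass. MYC-responsive and ribosome biogenesis genes were higher as a list (mean 0.33, adjusted p = 4.2e-09), with 0 of 22 called over all genes and 14 higher when adjusted over the list alone. DNA replication (mean 0.42, adjusted p = 4.34e-08) had 0 of 28 called and 5 higher when adjusted over the list alone. G1/S genes (0.28, adjusted p = 0.0028) had 0 of 16 and 3, and cholesterol synthesis (0.25, adjusted p = 9.96e-06) had 0 of 19 and 4. Published miR-15 family targets were higher (mean 0.20, adjusted p = 0.00202), with 1 of 27 called, Arl2 (1.12 ± 0.10, adjusted p = 0.0127), and 6 when adjusted over the list alone. The unfolded protein response was higher (mean 0.45, adjusted p = 1.16e-04), with 5 of 17 genes higher and 0 lower, 5 and 0 when adjusted over the list alone, among them Atf3 (0.78). In a split made after the values were seen, the 7 members linked to the factor ATF4 had a mean of 0.99 with 5 higher. The other 10 had a mean of 0.07 and 0 called. Made after the values, the split describes them and does not test whether the parts differ. With an estimated correlation, adjusted p = 0.395 for the MYC-responsive genes, 0.584 for DNA replication, G1/S genes and targets, 0.273 for cholesterol synthesis and 0.506 for the unfolded protein response.

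Other lists were lower with IL-7. Pre-B differentiation factors (mean -0.36, adjusted p = 6.42e-04) had 2 of 18 lower and 4 when adjusted over the list alone. Immature and mature B cell markers (-0.27, adjusted p = 0.00484) had 1 of 18 lower and 5 when adjusted over the list alone. The 1 marker was Cd40 (-1.60, adjusted p = 0.0433, and adjusted p = 0.076 with replicate as a block). Pre-BCR and B lineage signalling was lower (-0.14, adjusted p = 0.0092), with 0 of 17 called and 3 lower when adjusted over the list alone. Lysosome and autophagy genes were lower (-0.12, adjusted p = 0.0101), with 3 of 21 lower and 4 when adjusted over the list alone. The 3 were Neu1 (-1.15), Gabarapl1 (-1.02) and Ctss (-0.68). CDK inhibitors and quiescence genes passed as lower (mean -0.23, median 0.01, adjusted p = 0.0382), with 3 of 16 lower and 6 when adjusted over the list alone. The called genes were Mxd4 (-1.30), Tob1 (-0.80) and Klf2 (-0.79), which restrain proliferation. With an estimated correlation, adjusted p = 0.506 for the pre-B list, 0.603 for lysosome genes and 0.584 for the other 3.

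Called genes with a symbol that lay far apart with IL-7 included Coro2a (-9.88 ± 0.24, well above background on 1 of 2 sponge arrays), Glra4, at least 327-fold lower, and Il20ra, at least 14.9-fold lower. Higher ones included Gjd3 (7.38 ± 0.95), Il31ra, at least 32.9-fold higher, Adap2 (4.98 ± 0.37) and Comp (4.58 ± 0.55). The probes of these 7 and of Lipt2 (-2.80 ± 0.09) hold a short word shared among such features or the 7-base miR-15 seed match, and the other kept probe of Coro2a gave 0.88. The words were drawn from a set that includes these 7, so holding one is no independent evidence for them. Of the 30963 kept probes, 1063 hold such a word or the match. The Coro2a probe lies on chromosome 4 from 46556251 to 46556310 and that of Gjd3 on chromosome 11 from 98843494 to 98843553 (mm9). Further called genes were Vmn2r7, at least 3.01-fold higher, Jdp2 (2.84, well above background on 1 of 2 scrambled arrays), Pinlyp, at least 3.52-fold lower, and the receptor Tnfrsf14 (-2.88, its other kept probe -0.48). Of the genes fixed for every comparison, Ccnd3 (0.21), Ccnd2 (-0.33), Cdk6 (0.32), Bcl2 (0.12), Blnk (-0.32), Il7r (0.15), Socs2 (-0.10), Myc (-0.06), Igkc (-0.03), Igll1 (-0.19), Dleu2 (0.14) and Smc4 (0.19) did not pass.

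Mitosis genes did not pass with IL-7 (0 of 29 called, 0 when adjusted over the list alone, adjusted p = 0.054, and 0.0477 with replicate as a block). The IL-7 receptor and STAT5 pathway (0 higher and 2 lower, adjusted p = 0.0765) and glycolysis (0 called, adjusted p = 0.111) did not pass either. Apoptosis regulators did not (0 and 1, adjusted p = 0.655), although Bmf, a pro-apoptotic BCL2 relative, was lower (-1.16). Nor did p53 targets (1 and 2, adjusted p = 0.972), interferon response genes (0 called, adjusted p = 0.294), heat shock genes (0 called, adjusted p = 0.972) or microRNA processing genes (1 and 0, adjusted p = 0.707). Marker lists of T cells (0 called, adjusted p = 0.972), myeloid (0 and 1, adjusted p = 0.607), NK (0 and 1, adjusted p = 0.566), erythroid (0 called, adjusted p = 0.972) and plasma cells (0 called, adjusted p = 0.607) did not pass, and 0 of 3 fibroblast markers were called (mean 0.32). When adjusted over the list alone, 2 and 2 p53 targets, 2 and 0 microRNA processing genes, 0 and 2 T cell markers and 1 and 1 NK markers were higher and lower, and the other counts were the same. Mean, median and test did not share a sign for the apoptosis, heat shock, T cell and erythroid lists. The count of 241 depended on single arrays, being 155 without scrambled cells with IL-7 replicate 1 and 1360 without replicate 2, where the balance turned to 837 higher and 523 lower. It was 38 and 40 without sponge cells with IL-7 replicates 1 and 2, 93 without either scrambled array without IL-7, and 83 without either sponge array without IL-7. Of the 34 named called genes, 5 passed in all 8 of these fits, namely Coro2a, Glra4, Il20ra, Lipt2 and Trib3.

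The fourth comparison set the constructs side by side 36 h after withdrawal. Genes of the cell cycle were higher and genes of B cell maturation lower with the miR-15 sponge. Ccne1 was higher by 3.22 ± 0.30 (adjusted p = 0.00143) and its second kept probe by 2.82, where the first lies on chromosome 7 from 38882937 to 38882960 (mm9) and holds the 7-base seed match. Bcl2 was higher by 1.47 ± 0.09 (adjusted p = 0.00111), Myc by 1.04 ± 0.09 (adjusted p = 0.00129) and Mcm6 by 2.35 ± 0.23 (adjusted p = 0.00148). Rag1 was lower (-2.56 ± 0.27, adjusted p = 0.00173) and so was Cd40 (-2.38 ± 0.22, adjusted p = 0.00141). In all, 6843 genes passed, 3572 higher and 3271 lower, of which 994 and 553 changed by 2-fold or more. The larger direction was not stable, with 3531 higher and 3973 lower after quantile normalization, 3286 and 3548 with normexp, 3585 and 3866 in the deposited value table and 3673 and 4016 with only the arrays compared.

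Without IL-7, 27 of 28 DNA replication genes were higher with the sponge and 0 lower, 27 and 0 when adjusted over the list alone (mean 1.86, adjusted p = 1.38e-17). Cdc6 stood at 2.76 and the DNA polymerase subunit Pola1 at 2.55. All 29 mitosis genes were higher, 29 when adjusted over the list alone (mean 1.2, adjusted p = 1.56e-16). Foxm1 stood at 1.71 and Top2a at 1.58, and Aurkb was at least 1.47-fold higher. Of 16 G1/S genes, 13 were higher and 1 lower, 14 and 1 when adjusted over the list alone (mean 1.19, adjusted p = 4.89e-07), including E2f8 (2.15) and E2f1 (2.06). The lower G1/S gene was Ccnd2, a published target that encodes cyclin D2 (-0.57, adjusted p = 0.0231). Of 27 published miR-15 family targets, 16 were higher and 4 lower, 17 and 4 when adjusted over the list alone (mean 0.70, adjusted p = 3.62e-05). Among them were Wee1 (1.81), Arl2 (1.68) and Nusap1 (1.52). Of 22 MYC-responsive genes, 13 were higher and 1 lower, 15 and 1 when adjusted over the list alone (mean 0.42, adjusted p = 1.33e-05), including Nme1 (1.05, its probes between 0.50 and 1.05) and Srm (0.95). Unfolded protein response genes had 10 of 17 higher and 1 lower, 10 and 1 when adjusted over the list alone (mean 0.49, adjusted p = 0.00295). Atf3 was at 1.75 and Chac1 at 1.58. The mean was 0.86 for the 7 members linked to ATF4 (5 higher and 0 lower) and 0.23 for the other 10 (5 higher and 1 lower). For these 6 lists, adjusted p = 0.363 with an estimated correlation. Cholesterol synthesis had 14 of 19 higher and 0 lower, 18 and 0 when adjusted over the list alone (mean 0.65, adjusted p = 6.19e-09, and adjusted p = 0.118 with an estimated correlation). Fdps was at 1.27 and Sqle at 1.18.

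The lists that were lower with the sponge after withdrawal held differentiation genes and lysosome genes. Pre-B differentiation factors had 11 of 18 lower and 0 higher, 13 and 0 when adjusted over the list alone (mean -0.52, adjusted p = 2.2e-04), among them Rag2 (-1.71) and the lymphoid factor Ikzf3 (-0.61). Immature and mature B cell markers had 10 of 18 lower and 0 higher, 10 and 0 when adjusted over the list alone (mean -0.66, adjusted p = 0.00314), including Cd69 (-1.87) and the cytokine gene Ltb (-1.83). Pre-BCR and B lineage signalling had 8 of 17 lower and 0 higher, 8 and 0 when adjusted over the list alone (mean -0.27, adjusted p = 0.00549), including Cd22 (-0.58) and the kinase Lyn (-0.44). For these 3 lists, adjusted p = 0.363 with an estimated correlation. Lysosome and autophagy genes had 9 of 21 lower and 0 higher, 12 and 0 when adjusted over the list alone (mean -0.44, adjusted p = 5.62e-04, and adjusted p = 0.429 with an estimated correlation), including Gabarapl1 (-1.56) and Neu1 (-1.47).

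Of the genes fixed for every comparison, Ccnd3 (0.66) and Smc4 (1.0) were higher with the sponge without IL-7, and Cish (-1.33), Socs2 (-0.37) and Blnk (-0.55) were lower. Cdk6 (0.51, adjusted p = 0.0559), Igkc (-0.17), Il7r (0.14), Igll1 (-0.13) and Dleu2 (-0.08) did not pass. Called genes far apart again included Coro2a (-10.05, its other probe -0.78), Glra4, at least 478-fold lower, Il20ra, at least 24.3-fold lower, and Lipt2 (-3.37) on the lower side. Those on the higher side were Gjd3 (6.98), Comp (6.23), Il31ra, at least 32.2-fold higher, and Adap2 (5.27), joined by Pth (8.15 ± 1.92) and Npas1 (7.86 ± 1.11). The probes of Pth and Npas1 also hold such a shared word or the seed match, and both genes and Comp were well above background on 1 of 2 scrambled arrays. Pth and Npas1 also belong to the set from which the words were drawn. Kynu, at least 2.57-fold lower, and Myo7a (-2.80) followed.

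CDK inhibitors and quiescence genes did not pass without IL-7 (6 of 16 higher and 7 lower, mean 0.13, median -0.16, adjusted p = 0.975), with Cdkn1a at 1.83 (its 3 kept probes between 0.37 and 1.83) and Klf2 at -1.63. The IL-7 receptor and STAT5 pathway (2 and 9, adjusted p = 0.133) and glycolysis (7 and 2, 9 and 2 when adjusted over the list alone, adjusted p = 0.0528) did not pass. The same held for apoptosis regulators (3 and 4, adjusted p = 0.916), p53 targets (2 and 4, adjusted p = 0.554) and interferon response genes (1 and 5, mean -0.16, median 0.03, adjusted p = 0.67). Heat shock genes (3 and 3, adjusted p = 0.888) and microRNA processing genes (3 and 4, adjusted p = 0.814, with Dgcr8 at 1.16) did not pass. It held too for T cell (2 and 1, adjusted p = 0.975), myeloid (0 and 1, adjusted p = 0.25), NK (0 and 1, adjusted p = 0.419), erythroid (0 called, adjusted p = 0.814) and plasma cell markers (1 and 4, adjusted p = 0.263). Of 3 fibroblast markers, 0 were called (mean -0.04). When adjusted over the list alone, the counts were 6 and 8 for CDK inhibitors, 4 and 4 for apoptosis regulators, 2 and 5 for p53 targets, 3 and 4 for heat shock and 3 and 6 for microRNA processing genes, and the same as above for the others. Mean, median and test did not share a sign for the CDK inhibitor, apoptosis, interferon, T cell and erythroid lists. The count of 6843 fell to 4138 and 3416 without scrambled cells without IL-7 replicates 1 and 2, and to 4110 and 4329 without sponge cells without IL-7 replicates 1 and 2.

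**Figure D3:**
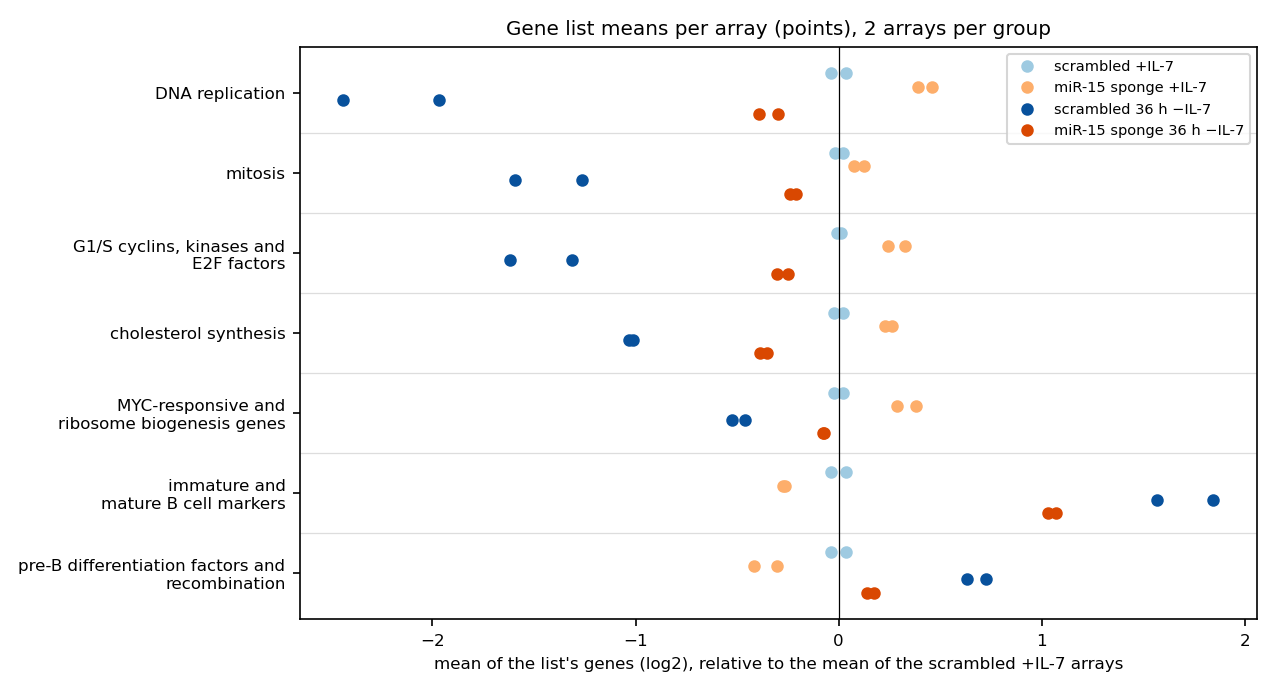
Mean log2 signal of 7 gene lists on each of the 8 arrays, relative to the mean of the scrambled arrays with IL-7. DNA replication genes stood at -1.97 and -2.44 on the scrambled arrays without IL-7 and at -0.30 and -0.39 on the sponge arrays without IL-7.

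Averaged over both conditions, cell cycle and MYC-responsive genes and a part of the unfolded protein response genes were higher with the miR-15 sponge, and recombination and maturation genes were lower. Ccne1 was higher by 1.93 ± 0.21 (adjusted p = 0.00248), and its second probe by 1.60, and Trib3 was higher by 1.43 ± 0.05 (adjusted p = 0.0002). Rag1 was lower (-2.48 ± 0.19, adjusted p = 0.00147), as was Cish (-1.19, adjusted p = 0.00106). In all, 6761 genes passed, 3623 higher and 3138 lower, of which 324 and 235 changed by 2-fold or more. Here too the larger direction turned, with 3450 higher and 3657 lower after quantile normalization, 3370 and 3436 with normexp and 3513 and 3543 in the deposited value table. The study's description implies that a clone gave 1 array with and 1 without IL-7. The fit treats these arrays as independent, so the SEs and adjusted p values of the averaged effect may be too small.

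In the averaged effect, 16 of 27 published miR-15 family targets were higher and 2 lower, 17 and 3 when adjusted over the list alone (mean 0.45, adjusted p = 3.79e-05). Other higher targets included Arl2 (1.40), Wee1 (1.18) and the phosphatase Cdc25a (0.92). DNA replication had 27 of 28 higher and 0 lower, 27 and 0 when adjusted over the list alone (mean 1.14, adjusted p = 1.48e-15). Mitosis had 28 of 29 and 0, 29 and 0 when adjusted over the list alone (0.65, adjusted p = 2.95e-13), and G1/S genes 14 of 16 and 1, 14 and 2 when adjusted over the list alone (0.74, adjusted p = 3.11e-06). MYC-responsive genes had 17 of 22 higher and 0 lower (0.38, adjusted p = 2.28e-07), and the unfolded protein response 8 of 17 and 1 (0.47, adjusted p = 6.11e-04). Its 7 members linked to ATF4 had a mean of 0.93 (5 higher and 1 lower) and the other 10 of 0.15 (3 higher and 0 lower). Cholesterol synthesis had 17 of 19 and 0 (0.45, adjusted p = 1.18e-08), and glycolysis had 8 of 17 and 1 (0.14, adjusted p = 0.0376, but 0.0622 after quantile normalization). Lower lists, each with 0 higher, were pre-B factors (10 of 18 lower, mean -0.44, adjusted p = 1.29e-04) and immature and mature B cell markers (9 of 18, -0.46, adjusted p = 0.00104). Pre-BCR signalling (6 of 17, -0.21, adjusted p = 0.00233) and lysosome genes (8 of 21, -0.28, adjusted p = 0.00104) were lower too, with 0 higher. Adjusted over the list alone, 10 and 1 unfolded protein response genes and 18 and 0 cholesterol synthesis genes were higher and lower. By the same measure 11 pre-B factors, 10 mature B cell markers and 11 lysosome genes were lower, and the MYC-responsive, glycolysis and pre-BCR counts did not move. With an estimated correlation, adjusted p = 0.346 for mitosis, 0.125 for cholesterol synthesis, 0.494 for glycolysis, 0.472 for lysosome genes and 0.34 for the other 8.

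Bcl2 (0.79 ± 0.07), Myc (0.49), Ccnd3 (0.43), Cdk6 (0.41) and Smc4 (0.59) were higher in the averaged effect, and Rag2 (-1.63), Ccnd2 (-0.45), Blnk (-0.44) and Socs2 (-0.24) were lower. Il7r (0.14), Igkc (-0.10), Igll1 (-0.16) and Dleu2 (0.03) did not pass. Called genes far apart included Coro2a (-9.97, its other probe 0.05, with 1 of 2 sponge arrays with IL-7 well above background) and Gjd3 (7.18). Both have a probe that holds such a shared word or the seed match, and both belong to the set from which the words were drawn. The lists that did not pass were CDK inhibitors (5 higher and 7 lower, adjusted p = 0.699), the IL-7 receptor and STAT5 pathway (3 and 9, adjusted p = 0.132), and apoptosis regulators (3 and 4, adjusted p = 0.946). Others were p53 targets (3 and 5, adjusted p = 0.7), interferon response (0 and 5, adjusted p = 0.563), heat shock (4 and 4, adjusted p = 0.852) and microRNA processing (2 and 2, adjusted p = 0.852). Marker lists of T cells (2 and 1, adjusted p = 0.94), myeloid (0 and 2, adjusted p = 0.367), NK (0 and 1, adjusted p = 0.548), erythroid (0 called, adjusted p = 0.852) and plasma cells (1 and 2, adjusted p = 0.367) did not pass. Of 3 fibroblast markers, 0 were called (mean 0.14). When adjusted over the list alone, the counts were 6 and 7 for CDK inhibitors, 4 and 9 for the IL-7 receptor and STAT5 pathway, 3 and 6 for p53 targets, 3 and 3 for microRNA processing, 0 and 1 for myeloid and 1 and 4 for plasma cell markers, and the same as above for the others. Mean, median and test did not share a sign for the apoptosis, interferon, microRNA processing, T cell and erythroid lists. The count of called genes fell to 4151 without scrambled cells without IL-7 replicate 2. Across genes, the sponge effects with and without IL-7 had a Pearson correlation of 0.537 and a Spearman correlation of 0.527. All 225 genes called in both had the same sign, 63 higher where 11.2 are expected by chance and 162 lower where 26.7 are expected. The expected numbers assume independent comparisons, while by the study's description both used the same clones.

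The last comparison asked whether the response to withdrawal differed between the constructs, as the change in sponge cells minus that in scrambled cells. Cell cycle genes that fell in control cells fell less with the sponge, and the recombination genes did not differ detectably. Ccne1 differed by 2.58 ± 0.43 (adjusted p = 0.0354, and 0.053 with replicate as a block) and by 2.45 at its second probe. Bcl2 differed by 1.35 ± 0.13 (adjusted p = 0.0306, 0.0508 with the block) and Myc by 1.1 ± 0.12 (adjusted p = 0.0306, 0.0508 with the block). Rag1 gave -0.17 ± 0.38 (adjusted p = 0.825), Rag2 -0.15 ± 0.26 and Igkc -0.14 ± 0.23. In all, 1124 genes passed, 921 with a positive difference and 203 with a negative one, of which 448 and 79 differed by 2-fold or more. The split depended on the scaling, with 1215 and 457 after quantile normalization, 1204 and 437 with normexp and 1225 and 452 in the deposited value table. An unadjusted p under 0.05 was reached by 4944 genes, where 1066 are expected by chance. With replicate as a block, limma called 0 genes, with a smallest adjusted p of 0.0508 and 5105 genes at an unadjusted p under 0.05.

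Of 28 DNA replication genes, 23 had a positive difference and 0 a negative one, 27 and 0 when adjusted over the list alone (mean 1.43, adjusted p = 6.1e-21). Cdc6 differed by 2.22 and Mcm6 by 1.91. Mitosis had 21 of 29 and 0, 29 and 0 when adjusted over the list alone (mean 1.1, adjusted p = 4.27e-21), including the kinesin Kif11 (1.48) and Foxm1 (1.47). G1/S genes had 8 of 16 and 0, 12 and 0 when adjusted over the list alone (mean 0.90, adjusted p = 7.43e-08), including E2f1 (1.44). Published miR-15 family targets had 10 of 27 and 0, 14 and 2 when adjusted over the list alone (mean 0.50, adjusted p = 2.79e-04), including Nusap1 (1.35). Cholesterol synthesis had 4 of 19 and 0, 11 and 0 when adjusted over the list alone (mean 0.41, adjusted p = 1.13e-06), including Fdps (0.84). CDK inhibitors and quiescence genes had 5 of 16 and 1, 7 and 2 when adjusted over the list alone (mean 0.36, adjusted p = 0.0304, a call lost after quantile normalization). Cdkn1a (1.61, its 3 kept probes between 0.12 and 1.61), Rbl1 (1.46) and Cdkn2c (1.12) are cell cycle inhibitors that were lower after withdrawal in control cells. Immature and mature B cell markers passed as negative (mean -0.39, adjusted p = 0.0327), with 2 of 18 lower, Cd69 (-1.98) and Tnfrsf13c (-0.66), and 3 when adjusted over the list alone. So did lysosome genes (mean -0.32, adjusted p = 0.00553), with 1 of 21 lower, Ctss (-0.64), 1 when adjusted over the list alone. With an estimated correlation, adjusted p = 0.506 for the replication, mitosis and G1/S lists, 0.213 for cholesterol synthesis and 0.634 for the other 4.

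Called genes outside the lists included the immediate early gene Arc (2.45) and Tnfrsf14 (2.96, its other kept probe 0.02). Ccnd3 (0.45), Ccnd2 (-0.24), Cdk6 (0.18), Cish (-0.29), Il7r (-0.01), Blnk (-0.22), Socs2 (-0.26), Igll1 (0.06), Dleu2 (-0.22) and Smc4 (0.81, adjusted p = 0.0596) did not pass. The lists that did not pass were the IL-7 receptor and STAT5 pathway (2 positive and 1 negative, adjusted p = 0.31), pre-B factors (0 called, adjusted p = 0.0803), and pre-BCR signalling (0 called, adjusted p = 0.247). Nor did MYC-responsive genes (1 and 0, adjusted p = 0.31, with Nme1 at 0.76 and its 3 probes between -0.08 and 0.76) or glycolysis genes (2 and 0, adjusted p = 0.31) pass. The same held for apoptosis regulators (2 and 0, adjusted p = 0.744), p53 targets (2 and 0, adjusted p = 0.845), the unfolded protein response (2 and 1, adjusted p = 0.893). It held for interferon response (0 called, adjusted p = 0.833), heat shock (1 and 0, adjusted p = 0.844) and microRNA processing (1 and 0, adjusted p = 0.744). It held too for T cell (0 called, adjusted p = 0.893), myeloid (0 called, adjusted p = 0.31), NK (0 called, adjusted p = 0.573), erythroid (0 called, adjusted p = 0.844) and plasma cell markers (1 and 0, adjusted p = 0.31). Of 3 fibroblast markers, 0 were called (mean -0.36). When adjusted over the list alone, the counts were 5 and 2 for glycolysis, 2 and 3 for p53 targets, 2 and 2 for the unfolded protein response, 1 and 1 for heat shock, 0 and 1 for NK and 1 and 2 for plasma cell markers, and the same as above for the others. Mean, median and test did not share a sign for the apoptosis, p53 and unfolded protein response lists. The count of 1124 rested on nearly every array, since limma called 0 genes without either sponge array with IL-7 (3904 and 4689 at an unadjusted p under 0.05), without scrambled cells without IL-7 replicate 2 (3349), or without either sponge array without IL-7 (4043 and 4008). It called 12 without scrambled cells with IL-7 replicate 1 and 1616 without replicate 2 (892 positive and 724 negative). It called 793 without scrambled cells without IL-7 replicate 1, and 0 of the 48 named called genes passed in all 8 of these fits.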

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

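Of the tests in this part, those of chance differences between clones, of probes reading another transcript, of the withdrawal ratio under other scalings and of a uniformly weaker withdrawal were chosen only after the result was seen. The withdrawal response differed between the constructs for 1124 genes by the test of the difference itself, and so did Ccne1 (2.58), Bcl2 (1.35) and Myc (1.1). With camera, which tests lists, it differed for published miR-15 family targets (mean difference 0.50), G1/S genes (0.90), DNA replication (1.43), mitosis (1.1), CDK inhibitors and quiescence genes (0.36), immature and mature B cell markers (-0.39), cholesterol synthesis (0.41) and lysosome genes (-0.32). All 8 lists passed with replicate as a block too, and 0 passed with an estimated correlation (adjusted p = 0.213 to 0.634 with an estimated correlation). With single arrays left out, the mature B cell list lost its call without 4 of the 8 arrays, the CDK inhibitor list without 3 and the lysosome list without 1. The calls of single genes rest on few arrays, since with replicate as a block limma called 0 genes (5105 at an unadjusted p under 0.05). It also called 0 without either sponge array with IL-7 (3904 and 4689 unadjusted), either sponge array without IL-7 (4043 and 4008) or scrambled cells without IL-7 replicate 2 (3349), 12 without scrambled cells with IL-7 replicate 1, 1616 without replicate 2 of that group (892 positive and 724 negative), and 793 without scrambled cells without IL-7 replicate 1.

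A set of 18 features lay at least 16-fold apart between the constructs both with and without IL-7, 12 higher and 6 lower with the sponge. Regrouping the 4 clones by replicate number or crosswise gave 0 such features each, but these 3 groupings are too few for a share under 0.05. Of the 12 higher features, 33.3% have a probe with the 7-base miR-15 seed match, against 1.09% of all 30963 kept probes, and 5 of the 6 lower features share an 8-base word, where random sets of as many probes reached 3. Probes reading another transcript than the named gene, such as the sponge or the scrambled RNA, are therefore a candidate explanation. Of 9 other kept probes of 4 of these genes or regions, 0 followed. Coro2a, with 1 other probe, was the only named gene among the 4. The others were genomic regions, whose probes need not read the same transcript. A biological change stays open at these regions and at genes where no second probe was kept. The vector sequence that would decide it was not at hand.

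Withdrawal changed gene expression less in cells with the miR-15 sponge. Scaling between arrays is argued against, since the median ratio of sponge to scrambled change among genes that fell was at most 0.450 under the other scalings. A uniformly weaker withdrawal is argued against too, since the ratios of the mitosis and the mature B cell lists differed by 4.75 standard errors. These were the lowest and the highest of 5 lists, a choice that the standard error does not allow for. Both lists were read on the same arrays, and only the main scaling was used. Within replicates 1 and 2 the ratios were 0.223 and 0.231 for mitosis, and 0.806 and 0.743 for mature B cell markers. Open are a gene-dependent response to a remainder of IL-7, the position of the arrays, whose slide rows follow the construct, and an effect of the miR-15 family itself, which the design names and which may keep cell cycle genes up. None of these 3 was tested.

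Few genes were called between the constructs with IL-7, 241 against 6843 without. The more variable replicates of scrambled cells with IL-7 raise the question of a deviating array, but leaving out replicate 1 of that group gave 155 genes, fewer than the 1360 without replicate 2. These counts cannot decide it, because each comes from a fit with 1 scrambled array with IL-7 left. Without replicate 2, that array is replicate 1 itself. On the second principal component, replicate 1 lay at 57.21 and replicate 2 at 19.96. The sponge arrays with IL-7 lay at -12.91 and -15.27. A deviating replicate 1 therefore stays open. The count also fell to 38 and 40 without sponge arrays 1 and 2 with IL-7, to 93 without either scrambled array without IL-7 and to 83 without either sponge array without IL-7. A smaller effect of the sponge while IL-7 is present, the biological alternative, may account for the difference, and 1124 genes differed between the conditions by the test of the difference, but with replicate as a block limma called 0 (5105 at an unadjusted p under 0.05).

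For the sponge effect averaged over both conditions, 3861 genes were called by a fit of the construct beside the IL-7 term, against 6761 by the model of the 4 groups. Of 34 splits of the 8 arrays into 4 and 4 that could be fitted this way, 1, the real one, gave as many genes, and the highest other split gave 86. The study's description implies that a clone gave 1 array with and 1 without IL-7, and 31 of these splits part such arrays. The 3 splits that keep them together are too few for a share under 0.05, with 0 genes called in the other 2. Slide row follows the construct, so the splits do not separate those.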

How the results depend on the processing

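The setting that left out probes with construct-specific words was chosen only after the result was seen, and the other settings here were planned. The blocks for slide and scan were not run because all 8 arrays share 1 slide and 1 scan, and neither were the tests of seed matches in 3′ untranslated regions and their alternatives, for lack of sequence. Genes that a stricter filter or the word setting removed have no value there. Low signal limits the comparisons, since only 50.6% to 56.6% of spots were well above background.

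Of 144 list shifts, 68 of them called, 131 to 144 kept their direction and their side of the threshold under each scaling, probe summary, block and moderation, and 133 did with no filter. With an estimated correlation all 68 calls were lost, and with fry 12 were lost and 17 gained. Of 514 values of named genes, 447 to 509 held in the same settings and 416 with no filter. Of the named calls, 79 of 87 for withdrawal in scrambled cells, 45 of 79 in sponge cells, 5 of 34 for the sponge with IL-7, 71 of 80 without, 73 of 85 averaged and 0 of 48 for the difference held with each array left out. With fry, the microRNA processing list turned direction without IL-7 (mean -0.0091) and averaged (0.0106), and the cause was not tested.

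Counts that moved by more than 1.5 times were as follows, where the cause was not tested unless given. With normexp 388 genes were called for the sponge with IL-7, and the averaged values of Aurkb and Tcf7 turned to -0.0137 and -0.0032. With no filter, where more dim probes were tested, 2644 were called for withdrawal in sponge cells, 82 for the sponge with IL-7 and 0 for the difference (4744 at an unadjusted p under 0.05), and the correlation of the sponge effects was 0.342 and that of the withdrawals 0.508. Only probes well above background on all 8 arrays gave 432 and 1716 for the sponge with IL-7 and the difference, the replicate block 151 and 0, and moderation with trend and robust 1030 and 2369. Only the arrays compared gave 4 for the sponge with IL-7. The same setting without IL-7 has as few residual degrees of freedom, and its count did not fall. Fewer degrees of freedom alone therefore do not account for the 4. A minimum change of 1, which by construction can only lower counts, left 2781, 599, 112, 1547, 559 and 527 in the order of the contrasts. Quantile normalization turned the withdrawal values of Igll1 in scrambled cells (0.0235) and Ccnb2 in sponge cells (0.001), as did the deposited value table (0.0591 and 0.0167). Without the construct-specific words, Coro2a, represented by its other probe, gave 0.88 with IL-7 and 0.054 averaged. With each array left out in turn, the counts were 6770 to 10356 and 1738 to 5141 for withdrawal in scrambled and sponge cells, 38 to 1360, 3416 to 7447 and 4151 to 7925 for the sponge with IL-7, without and averaged, and 0 to 1616 for the difference.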

Other observations

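The lists of amino acid response genes and of targets outside the cell cycle lists were chosen only after the results on the lists they extend were seen, the first before the values of its own members. Their p values are not adjusted over lists. They cannot be set beside the adjusted p values of the lists above, also with an estimated correlation. Genes of the amino acid response, which include those of amino acid transporters, synthesis enzymes and tRNA synthetases, fell on withdrawal in scrambled cells. Of 25 measured genes, 19 were lower and 0 higher (mean -0.81, camera p = 6.27e-07, and p = 0.0264 with an estimated correlation). Mthfd2, an enzyme of mitochondrial folate metabolism, fell by 2.61, the arginine transporter Slc7a1 by 2.01 and the serine synthesis enzyme Psat1 by 1.95. In sponge cells 17 fell and 0 rose (mean -0.48, p = 9.95e-07, and p = 0.028 with an estimated correlation), with Mthfd2 at -0.83 and Psat1 at -0.84. The difference between the responses was positive (p = 0.000661), with 3 genes higher and 0 lower, but p = 0.0788 with an estimated correlation.

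Without IL-7, 18 of these 25 genes were higher and 2 lower with the miR-15 sponge (mean 0.72, p = 6.52e-08, and p = 0.0204 with an estimated correlation), with Mthfd2 at 2.36 and Slc7a1 at 2.13. A wider amino acid response was the hypothesis drawn from the higher Chac1, Trib3, Asns and Atf3 with IL-7, and the test on these genes outside that list gave p = 5.18e-10 (mean 0.39, 23 of 25 positive, and p = 0.0128 with an estimated correlation). With IL-7, 4 of the 25 were higher and 1 lower over all genes tested, 15 and 1 when adjusted over the list alone, with Slc7a5 at 0.93 and Shmt2 at 0.77 higher and Ddit4 at -1.09 lower. The wider rise may reflect stress signalling or the growth state of the cells, which this test cannot separate.

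Whether published miR-15 family targets rose apart from cell cycle genes in the averaged effect stays open. Of 17 measured targets in none of the 3 cell cycle lists, 7 were higher and 1 lower, 8 and 2 when adjusted over the list alone (mean 0.32, camera p = 0.00596, but p = 0.158 with an estimated correlation), including Arl2 (1.40), Wee1 (1.18) and Cdca4 (0.85). Wee1, Cdca4, Chek1 and Cdc27 among these 17 also act in the cell cycle, so the test does not separate targets from cell cycle genes.

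Probes that hold the 7-base miR-15 seed match were higher with the sponge on average. The 338 such probes had a mean averaged effect of 0.22 and a median of 0.12, with 2.37% of them over 2 against 0.113% of all probes. They passed camera at a p under 0.05 and ranked 1 from the top among the 210 words of the same base composition. The other probes of the same genes, 325 probes of 155 genes, had a mean of -0.0246, against 0.12 for the 162 probes with the match. On this subset neither group passed camera at a p under 0.05 in the averaged effect, while with IL-7 the probes with the match did and the others did not. The rise may therefore come from the probes reading the sponge transcript, although the difference between the 2 groups of probes was not tested. It cannot be read as evidence for or against an effect on the targets of the family.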
